A study of Homo sapiens with 8 samples.

How the data were processed

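Total RNA of K562 and KBM5 cells, grown in RPMI-1640 medium with fetal bovine serum, was extracted with a Direct-zol kit, labelled with biotin and measured on expression arrays, per the labels. There were 8 arrays, 1 for each of 4 treatments in 2 cell lines: control, OR21 (100 nM for 3 days), IM (imatinib, 1000 nM for 24 hours) and the combination. The values are deposited by the authors as a linear intensity for each probe set, and the software, summarization and normalization behind them are not given in the sources used here. The table held 24351 probe sets, of which 21448 were transcript clusters and 2903 others, with 612 negative and 2197 positive controls among the latter. Gene names came from the probe annotation supplied with the data: 17709 probe sets carried 1 gene symbol, giving 17687 different genes, and 3739 transcript clusters had no name here and were only counted. For the 20 genes with more than 1 probe set, the one with the highest mean over the 8 arrays was used.

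Intensities were analysed as log2(value) without further normalization. The background of each array was the 95th percentile of its negative control probe sets. Where one side of a comparison was not above it, a fold is given as a bound ("at least"), and where neither side was, no fold is given. Where only some arrays of a side were above it, the measured difference is given, and its size is not exact. The number of arrays limits the precision of all values. No treatment of a line had a second array, so 2 models borrowed their repeats from the design. The model of both lines (limma, line plus treatment, 3 residual degrees of freedom) used the lines as repeats. The model per line gave each line its own baseline, OR21 term and IM term (2 residual degrees of freedom), and used as repeats the 2 disjoint array pairs of each drug within a line, with and without the other drug. Empirical Bayes moderation added 3.765 prior degrees of freedom to the first model and 8.309 to the second. P-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, and a gene was called at an adjusted p under 0.05. There were 12 contrasts: the effects of IM and of OR21 in both lines and in each line, the combination against control, against IM and against OR21, the interaction, and the difference between lines for each drug.

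The 27 gene lists (651 members) covered JAK-STAT targets, ERK output, FOXO targets, MYC targets and ribosome biogenesis, G1/S, G2/M, CDK inhibitors and p53 targets, the BCL2 family, globins, heme and iron, erythroid, megakaryocytic, granulocytic and monocytic, and stem and progenitor genes, cancer-testis antigens, interferon-stimulated genes, antigen presentation, DNA methylation and cytidine handling, unfolded protein and amino acid stress, cholesterol synthesis, glycolysis, lysosome and autophagy, NF-kB, replication-dependent histones, drug resistance, lymphoid and epithelial genes. They were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. The median of each list in each array pair was also ranked among 10000 random lists of the same size, matched in 50 bins of mean expression. The contrasts, gene lists, rule for naming genes and alternatives were fixed before the data were examined. Members not measured under their own symbol were matched by synonym. This put SLC25A21 in the place of ODC1 among MYC targets and EGFL7 in the place of NEU1 among lysosome genes. All counts, medians and tests of these lists include those genes.

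Genes named for a contrast, apart from members named for a list, moved the same way in every array pair of the contrast. For the effects of IM and OR21 in both lines and the combination against control, the 10 largest called rises and 10 largest called falls were named, for the other contrasts of that model 5 and 5, and for the model per line 6 and 6. Where fewer were called, the genes with the largest smallest-pair difference filled the list as values with no call. Up to 4 members of a gene list were named. XIST, Y-linked genes and symbols of unnamed or non-coding loci (22 genes of the first kinds, with TSIX) were counted but not named. Genes changed at least 2-fold in the same direction in both pairs of a line were counted without a test.

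The alternatives were quantile normalization, the brighter genes alone (mean log2 above that of the median gene), moderation with an intensity trend and robust fitting, the mean of a gene's probe sets, log2(value + 16), each array left out in turn, the line left out of the model of both lines, a common OR21 by IM term in the model per line, and 1.5-fold and 3-fold in place of 2-fold. With 1 array left out, its treatment kept 1 array in the model of both lines, and this array was assumed to vary like the others. In the model per line, each drug effect of the affected line then rested on 1 array pair, and the residual came from the other line. The procedure was tested on simulated data with 200 changed genes. In the model of both lines, 10.4% of 2-fold, 89.6% of 4-fold and 93.9% of 8-fold changes with IM were recovered, and for the combination against control 0%, 38.8% and 80.3%. In each of the 6 contrasts simulated there were 3 to 7 false calls. Lists were simulated in 2 of them, the IM effect in both lines and in KBM5, where camera called 0 of the 27 lists without a simulated change. The simulated genes varied independently of each other, so that count does not show how often camera falsely calls lists of correlated genes. In the data of both lines the estimated correlation of the G1/S list, for instance, was 0.963. A list lowered 2-fold was called at the preset correlation in both, and with an estimated correlation in both lines together (adjusted p = 0.025) but not in KBM5 (adjusted p = 0.133). Analyses used R 4.3.3 with limma 3.58.1, and figures Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No genome build or sequence-level analysis was used here.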

Results

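Gene expression was measured on 8 arrays, 1 for each of 4 treatments in the human chronic myeloid leukaemia lines K562 and KBM5. Chronic myeloid leukaemia cells depend on the fusion kinase BCR-ABL1, which imatinib (IM) inhibits. The treatments were no drug (control), OR21 at 100 nM for 3 days, IM at 1000 nM for 24 hours, and OR21 followed by IM (combination). OR21 is named in the series title as a demethylating agent. The label of the combination leaves out its OR21 dose, which was taken from the treatment protocol. The stated purpose was to find expression particular to the combination. Each line and treatment had 1 array, so no spread between repeats of a group was measured, and the number of arrays limits the precision of every value. The median intensity over all probe sets lay between 77.8 and 83.3 on the 8 arrays. Background, taken as the 95th percentile of the negative control probe sets, lay between 161 and 263, and between 5874 (KBM5 control) and 7084 (K562 OR21) of 17687 genes were above it.

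IM was compared with its absence over 4 array pairs, 2 in each line, to show what the drug did in both lines. SLC2A3, a high-affinity glucose transporter, fell by 5.51 ± 0.52 (SE) on the log2 scale, and its close paralog SLC2A14, whose probe sets may cross-hybridise with it, fell by 4.07 ± 0.28. SLC7A5, a transporter of large neutral amino acids, fell by 4.03 ± 0.40, and PHGDH, the first enzyme of serine synthesis, fell by 4.03 ± 0.70. The spermidine synthase gene SRM fell by 3.46 ± 0.22, the STAT5 target kinase PIM1 fell by 3.40 ± 0.63, and GAL, which encodes the neuropeptide galanin, fell by 3.69 ± 0.58. LRP8, a lipoprotein receptor, was at least 5.12-fold lower, the zinc transporter SLC39A14 at least 3.42-fold lower, and ETV5, a transcription factor downstream of ERK, at least 2.11-fold lower, each ending at background. With IM, SLC2A3 was above background on 1 of 4 arrays, PHGDH, GAL and PIM1 on 2 of 4 and SLC7A5 on 3 of 4, so the sizes of these falls are not exact.

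On the upper side, TP53INP1, a p53 target that promotes autophagy, was at least 3.43-fold higher with IM, starting from background. YPEL3, a growth-inhibiting gene of the yippee-like family, rose by 3.61 ± 0.20 on the log2 scale (12.2-fold), and its relative YPEL5 by 2.73 ± 0.23. The thiol methyltransferase gene TMT1A rose by 3.13 ± 0.22, the lipid transporter gene ABCA7 by 2.86 ± 0.49, and the autophagy receptor gene CALCOCO1 by 2.82 ± 0.24. ZER1, part of a ubiquitin ligase, rose by 2.63 ± 0.27, the nuclear receptor coactivator gene PNRC1 by 2.62 ± 0.20, ERMAP, a red cell membrane protein gene, 5.66-fold, and the mitochondrial kinase gene PDK2 by 2.49 ± 0.24. Without IM, ZER1 and ERMAP were above background on 2 of 4 arrays and YPEL3, TMT1A, CALCOCO1 and PDK2 on 3 of 4. All 20 of these genes moved the same way in 4 of 4 pairs, as the naming rule requires, with limma adjusted p between 0.00463 and 0.0332.

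Among the gene lists, MYC targets and ERK output fell with IM, and JAK-STAT targets did so mainly in K562. In the MYC target and ribosome biogenesis list, 18 of 25 measured genes fell, 22 when adjusted over the list alone, led by SRM, NOP16 (log2 difference -3.16 ± 0.25, above background on 3 of 4 arrays with IM), LDHA (-2.75 ± 0.25) and LYAR (-2.37 ± 0.31). The set test camera gave this list an adjusted p of 5.07e-20, and its call held with an estimated correlation (adjusted p = 0.0484). The 25 genes include SLC25A21, which the synonym match put in the place of ODC1. Of 19 genes of ERK output, 5 fell and 10 did when adjusted over the list alone, among them ETV5 and MYC itself (-2.31 ± 0.21). That list had a camera adjusted p of 1.74e-06, and adjusted p = 0.0827 with an estimated correlation. Of its 19 genes, 10 were at background on all K562 arrays and 10 on all KBM5 arrays, which limits what these falls show. Of 18 JAK-STAT targets, 5 fell, 6 over the list alone, including PIM1, CISH (-2.79 ± 0.43, above background on 2 of 4 arrays with IM) and ID1, which was at least 1.97-fold lower. Its camera adjusted p was 0.00347, and adjusted p = 0.461 with an estimated correlation. In KBM5 alone, 4 JAK-STAT targets rose and 5 fell, with a median of -0.11 and a camera adjusted p of 0.482. PIM1 went against the list, with -5.24 and -4.70 in the KBM5 pairs and -1.80 and -1.87 in the K562 pairs. The JAK-STAT list shares BCL6, which rose in KBM5, with the FOXO list. FOXO targets, which are held down by growth signalling, went up: 7 of 18 rose, 13 when adjusted over the list alone, with YPEL3, YPEL5, TXNIP (2.44 ± 0.28) and CITED2 (1.80 ± 0.27) the largest. Its camera adjusted p was 1.92e-09, and adjusted p = 0.0701 with an estimated correlation.

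Biosynthetic lists also fell with IM in both lines. In cholesterol and fatty acid synthesis, 11 of 20 genes fell, 17 when adjusted over the list alone, with DHCR7 at -3.21 ± 0.59, FASN at -2.85 ± 0.54 (above background on 2 of 4 arrays with IM) and SCD at -2.39 ± 0.48 (camera adjusted p = 1.39e-11, and adjusted p = 0.389 with an estimated correlation). In the list of unfolded protein and amino acid stress genes, 13 of 30 fell, 19 over the list alone with 1 rise, and the largest called falls were those of genes that import or make amino acids, SLC7A5, PHGDH, PSAT1 (-3.13 ± 0.39) and the asparagine synthetase gene ASNS (-2.84 ± 0.50, above background on 2 of 4 arrays with IM). Its camera adjusted p was 4.37e-10, and adjusted p = 0.0693 with an estimated correlation. Glycolysis and glucose uptake lost expression in 9 of 20 genes, 13 over the list alone with 1 rise, with SLC2A3, LDHA, ALDOC (-2.45 ± 0.55) and PGAM1 (-2.30 ± 0.30) the largest (camera adjusted p = 5.19e-09, and adjusted p = 0.126 with an estimated correlation). Lysosome and autophagy genes moved the other way, with 7 of 27 rising and 10 over the list alone, among them the lysosomal proteases TPP1 (1.63 ± 0.20) and CTSB (1.58 ± 0.28). Their camera adjusted p was 1.52e-06, and adjusted p = 0.461 with an estimated correlation. In K562 alone the camera adjusted p of this list was 0.0663, and 0.00312 after quantile normalization. Its 27 genes include EGFL7, which the synonym match put in the place of NEU1.

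Cell cycle lists had large mean falls over both lines but few single calls, because the lines differed. In the G1/S and DNA replication list 1 of 25 genes fell and 23 did when adjusted over the list alone, with values of -3.33 ± 1.06 for CDC45 and -2.93 ± 0.88 for RRM2, above background on 2 and 3 of 4 arrays with IM and neither called (camera adjusted p = 3.11e-10, and adjusted p = 0.461 with an estimated correlation). In the G2/M list 5 of 26 fell, 8 over the list alone, including CDC20 (-1.78 ± 0.40), KIF11 (-1.75 ± 0.39, above background on 2 of 4 arrays with IM) and TPX2 (-1.69 ± 0.37), with a camera adjusted p of 2.97e-10, and adjusted p = 0.461 with an estimated correlation. Replication-dependent histones had a median log2 difference of -1.01 over 18 genes with no single call in limma, where H2BC8 had -2.37 ± 0.78 (camera adjusted p = 1.87e-06, and adjusted p = 0.461 with an estimated correlation). Of 20 CDK inhibitor and p53 target genes, 4 rose, namely TP53INP1, SESN1 (at least 2.00-fold), CDKN1C (1.13 ± 0.19) and CDKN1B (1.03 ± 0.16), with a camera adjusted p of 0.264. In the BCL2 family of 15, the pro-apoptotic BMF, at background on all K562 arrays, rose at least 1.53-fold and BID fell by 1.32 ± 0.21, with a camera adjusted p of 0.603.

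Lineage lists and the remaining lists had few single calls in the analysis of both lines together. Of 23 erythroid regulator and membrane genes 3 rose, 5 over the list alone, ERMAP among them (camera adjusted p = 7.37e-05, and adjusted p = 0.461 with an estimated correlation). Of 18 heme and iron genes 1 rose (camera adjusted p = 0.05), and no gene of the globin list (9 genes, camera adjusted p = 0.0523) or the megakaryocytic list (18 genes, 0.05) passed in limma. The granulocytic and monocytic list of 25 had a median of 0.57 with CSF1R, at background on all K562 arrays, at least 1.16-fold higher and no single call (camera adjusted p = 0.00654, and adjusted p = 0.462 with an estimated correlation). Of 39 interferon-stimulated genes 3 rose and 1 fell, 6 and 1 over the list alone, with IFIH1 (1.42 ± 0.24) and SAMD9 (1.71 ± 0.40), at background on all K562 arrays, rising and BST2 (-1.44 ± 0.30, at background on both KBM5 arrays with IM) falling (camera adjusted p = 0.000589, and adjusted p = 0.201 with an estimated correlation). Most of the 39 were not detected, 32 being at background on all K562 arrays and 22 on all KBM5 arrays. The list of DNA methylation and cytidine handling genes had 3 of 17 fall, 7 over the list alone with 1 rise, among them the de novo methyltransferase gene DNMT3B (-1.84 ± 0.34, at background on all KBM5 arrays) and the nucleotide hydrolase gene DCTPP1 (-2.59 ± 0.21, above background on 3 of 4 arrays with IM), with a camera adjusted p of 0.00104, and adjusted p = 0.149 with an estimated correlation. Antigen presentation had 1 rise (TAPBP, 1.27 ± 0.17) and 1 fall (TAP2, at least 1.61-fold lower) among 17 genes (camera adjusted p = 0.367). The NF-kB list had 1 rise (TNFAIP2, 1.29 ± 0.27) and 1 fall (ICAM1, -0.91 ± 0.20) among 19, with a median of 0.02, a mean of -0.09 and a camera adjusted p of 0.469 in the downward direction. No gene of the lists for stem and progenitor cells (16 genes, median 0.01 and mean -0.26), cancer-testis antigens (47), drug resistance (12), lymphoid cells (13, median 0.09 and mean -0.06) or epithelial cells (14) passed in limma, and their camera adjusted p lay between 0.408 and 0.907. Camera put the stem and lymphoid lists downward, where their medians were above 0.

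**Figure D1:**
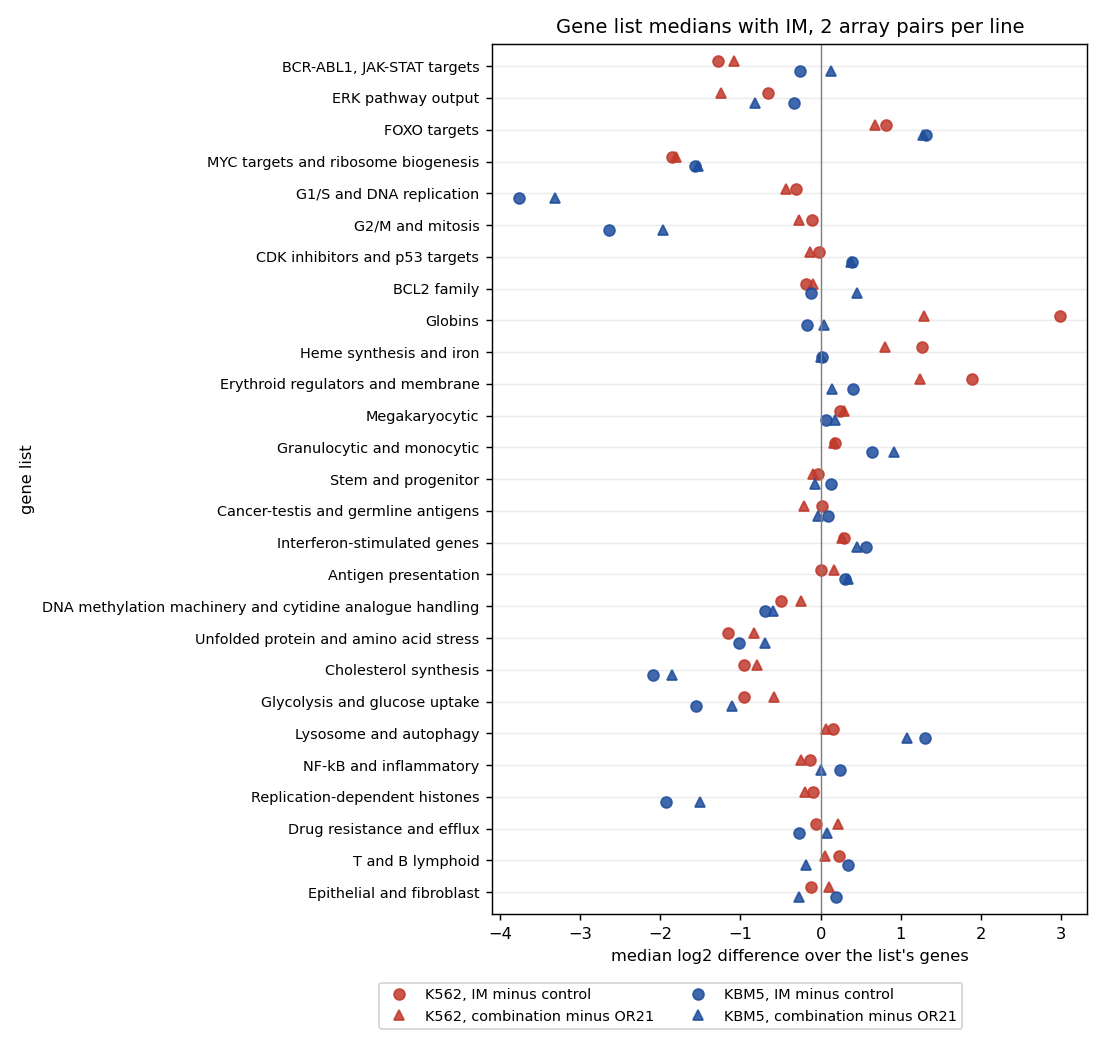
Median log2 difference over the genes of each of 27 lists (x axis), for IM minus control (circles) and combination minus OR21 (triangles), in K562 (red) and KBM5 (blue), with 1 array on each side of every difference. The G1/S list lies at -3.76 and -3.31 in KBM5 and at -0.31 and -0.43 in K562, while globins lie at 2.99 and 1.29 in K562.

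Limma called 487 higher and 862 lower with IM in both lines, and 4262 had an unadjusted p under 0.05. Quantile normalization changed the split to 598 higher and 631 lower, or from 36.1% to 48.7% higher. The p-values measure only the spread between these samples, here the difference in response between the lines. Leaving out 1 array lowered the 1349 calls for the IM effect, both lines together, to 557 without the K562 control, 200 without K562 OR21, 512 without K562 IM, 288 without the K562 combination, 311 without the KBM5 control, 115 without KBM5 OR21, 134 without KBM5 IM and 214 without the KBM5 combination. Of the 20 named genes, 14 kept their call with each array left out, while TP53INP1, ABCA7, ERMAP, PHGDH, GAL and PIM1 lost it at least once.

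In K562 alone, IM raised genes of the red cell programme, over 2 array pairs. SLC4A1, the red cell anion exchanger, was at least 9.81-fold higher, the carbonic anhydrase gene CA1 at least 18.0-fold, and ALAS2, the first enzyme of heme synthesis in red cells, rose by 5.96 ± 0.57 on the log2 scale. The membrane skeleton gene EPB42 rose by 5.86 ± 0.50, a size that is not exact because 1 of the 2 arrays without IM, the control, was below background. TUBB1, a tubulin of platelets, was at least 26.0-fold higher, and CYP3A5, a drug-metabolising enzyme, at least 28.0-fold. Of 9 globin genes 7 rose, led by HBB (3.89 ± 0.29), HBD (3.51 ± 0.40, above background on 1 of 2 arrays without IM) and HBE1 (3.10 ± 0.34), and the globin chaperone AHSP was at least 2.51-fold higher. Globin genes are close paralogs whose probe sets may cross-hybridise. Of 18 heme and iron genes 11 rose, including the mitochondrial iron importer SLC25A37 (3.81 ± 0.31) and FECH (3.35 ± 0.41), and of 23 erythroid genes 17 rose, including the blood group antigen gene KEL (4.48 ± 0.33). These 3 lists had camera adjusted p of 3.98e-08, 1.98e-07 and 5.78e-14, and adjusted p = 0.213, 0.165 and 0.296 with an estimated correlation.

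On the lower side in K562, EGR1, an early response gene of the ERK pathway, was at least 34.2-fold lower, and CD69, an activation antigen, at least 14.9-fold lower. The Fc receptor gene FCGR2A fell by 4.81 ± 0.24, SLC2A3, above background on 1 of 2 arrays with IM, fell by 6.13 ± 0.59, SLC2A14 fell by 4.63 ± 0.33, and CD3D, a T cell receptor subunit, was at least 3.33-fold lower. Of 18 JAK-STAT targets 9 fell, 10 over the list alone, among them the kinase PIM2 (-4.57 ± 0.25) and CISH, at least 6.18-fold lower (camera adjusted p = 1.5e-09, and adjusted p = 0.165 with an estimated correlation). ERK output lost 11 of 19 genes (1.35e-10), MYC targets 19 of 25 (3.45e-17), cholesterol synthesis 9 of 20 (2.37e-06) and FOXO targets gained in 8 of 18 (1.54e-06), each with adjusted p = 0.165 with an estimated correlation. Of the 19 ERK genes, 10 were at background on all K562 arrays, which limits what these falls show. In the BCL2 family 4 of 15 genes fell, among them the survival genes BCL2L1 (-2.20 ± 0.24, above background on 1 of 2 arrays with IM) and MCL1 (-1.72 ± 0.28), and 1 rose, BMF, at background on both sides (camera adjusted p = 0.194). Of 16 stem and progenitor genes 4 fell, among them MYB (-1.99 ± 0.24) and GATA2, at least 6.75-fold lower (camera adjusted p = 0.0626, and 0.0144 after quantile normalization). Of these 16 genes, 12 were at background on all K562 arrays, which limits what the list shows. Of 14 epithelial genes the keratins KRT8 (-2.36 ± 0.30) and KRT18 (-2.24 ± 0.27) fell (camera adjusted p = 0.249). In G1/S genes K562 had 1 rise, CDT1 (1.17 ± 0.32), and a list median of -0.39 (camera adjusted p = 0.0193, 0.363 after quantile normalization, and adjusted p = 0.628 with an estimated correlation). Over all genes limma called 944 higher and 1424 lower in K562, 39.9% higher against 50.5% after quantile normalization. The 2368 calls for the IM effect in K562 became 454 without the K562 control or K562 IM array, and 657 without the K562 OR21 or combination array. Each pair counts as a repeat only as far as the drugs add on the log2 scale, and 446 genes rose and 776 fell at least 2-fold in both pairs.

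In KBM5 alone, IM lowered the genes of DNA replication and mitosis. All 25 measured G1/S genes and all 26 G2/M genes fell over the 2 array pairs, including the replication helicase subunit CDC45 (at least 31.3-fold lower), the ribonucleotide reductase subunit RRM2 (-5.05 ± 0.36), TYMS (-4.84 ± 0.27), CDK1 (-3.43 ± 0.26) and TTK (-2.94 ± 0.31). RRM2 and CDK1 were above background on 1 of 2 arrays with IM, so their falls are not exact, and E2F1, of the G1/S list, was at background on all 8 arrays. Their camera adjusted p were 3.9e-31 and 7.59e-23, and adjusted p = 0.214 and 0.297 with an estimated correlation. Of 18 replication-dependent histones, a multicopy family whose probe sets may cross-hybridise, 16 fell, with H2BC8 at -4.16 ± 0.35 (camera adjusted p = 3.8e-13, and adjusted p = 0.304 with an estimated correlation). UBE2T, a ubiquitin conjugase of DNA repair, was at least 11.1-fold lower, PHGDH at least 18.0-fold, the glutamine transporter SLC38A5 at least 17.3-fold, and TBC1D30 at least 3.86-fold lower. Cholesterol synthesis fell in 18 of 20 genes, led by DHCR7 (-4.67 ± 0.27) and HMGCS1 (-4.33 ± 0.24), and MYC targets in 21 of 25, led by SRM (-3.72 ± 0.25). Both lists had adjusted p = 0.148 with an estimated correlation, against camera adjusted p of 4.68e-18 and 2.27e-16.

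Genes of monocytes and of the lysosome rose in KBM5 with IM. CSF1R, the macrophage growth factor receptor, was at least 6.52-fold higher, the scavenger receptor CD36 at least 8.63-fold, and GLIPR1 at least 26.0-fold. FYB1, an adaptor of immune cell adhesion, rose by 4.96 ± 0.27, MS4A6A by 4.59 ± 0.42, each above background on 1 of 2 arrays without IM, and TP53INP1 at least 4.15-fold. Of 25 granulocytic and monocytic genes 12 rose and 1 fell, 14 and 2 over the list alone, with CSF3R at 3.49 ± 0.27, above background on 1 of 2 arrays without IM, and LYZ at 3.47 ± 0.37 (camera adjusted p = 2.09e-05, and adjusted p = 0.205 with an estimated correlation). Of 27 lysosome and autophagy genes 18 rose, with GABARAPL1 at 3.54 ± 0.28, likewise, and CTSD at 2.06 ± 0.24, and of 18 FOXO targets 15 rose, with TXNIP at 3.01 ± 0.24 and the repressor BCL6 at least 4.46-fold higher. Those 2 lists had camera adjusted p of 3.05e-11 and 5.62e-10, and adjusted p = 0.148 and 0.156 with an estimated correlation. Of 39 interferon-stimulated genes 13 rose and 2 fell (camera adjusted p = 0.000831, and adjusted p = 0.214 with an estimated correlation). Of the 39, 22 were at background on all KBM5 arrays, which limits what these changes show. In the DNA methylation and cytidine handling list 7 of 17 genes fell, UHRF1 by 3.88 ± 0.32, while the nucleotide hydrolase SAMHD1 rose by 3.62 ± 0.24. That list had a camera adjusted p of 0.00233, and adjusted p = 0.304 with an estimated correlation. No globin gene passed in KBM5 in limma. Over all genes limma called 1912 higher and 1868 lower in KBM5, and 883 rose and 1096 fell at least 2-fold in both pairs.

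The effect of IM differed between the lines at 1796 genes by the test of the difference itself (KBM5 minus K562, 929 positive and 867 negative). All 25 G1/S genes, E2F1 at background among them, had a more negative effect in KBM5 (list median difference -3.32), as did 13 of 23 erythroid genes and 12 of 18 heme genes. Of 18 JAK-STAT targets, 11 had a more negative effect in K562 and 1 had it in KBM5. Of those 13 erythroid and 12 heme genes, 12 and 4 were at background on all KBM5 arrays, so for them the difference reflects a change in K562 alone. Of the 11 JAK-STAT targets, 2 were at background on all K562 arrays, where no fall could be measured, and 2 on all KBM5 arrays. Those 4 lists had camera adjusted p of 3.25e-31, 9.57e-09, 8.43e-08 and 6.28e-07, and adjusted p = 0.221, 0.263, 0.221 and 0.221 with an estimated correlation. Both lines shared 317 genes called higher, where independence would give 102, and 651 called lower, where it would give 150.4, although genes are not independent. Across genes, the 2 pairs within a line had Pearson r = 0.739 in K562 and 0.743 in KBM5, and pairs of different lines that share no array had r between 0.287 and 0.319. The 1796 calls for the IM effect, KBM5 minus K562, became 611 without the K562 control or K562 IM array and 718 without the K562 OR21 or combination array.

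**Figure D2:**
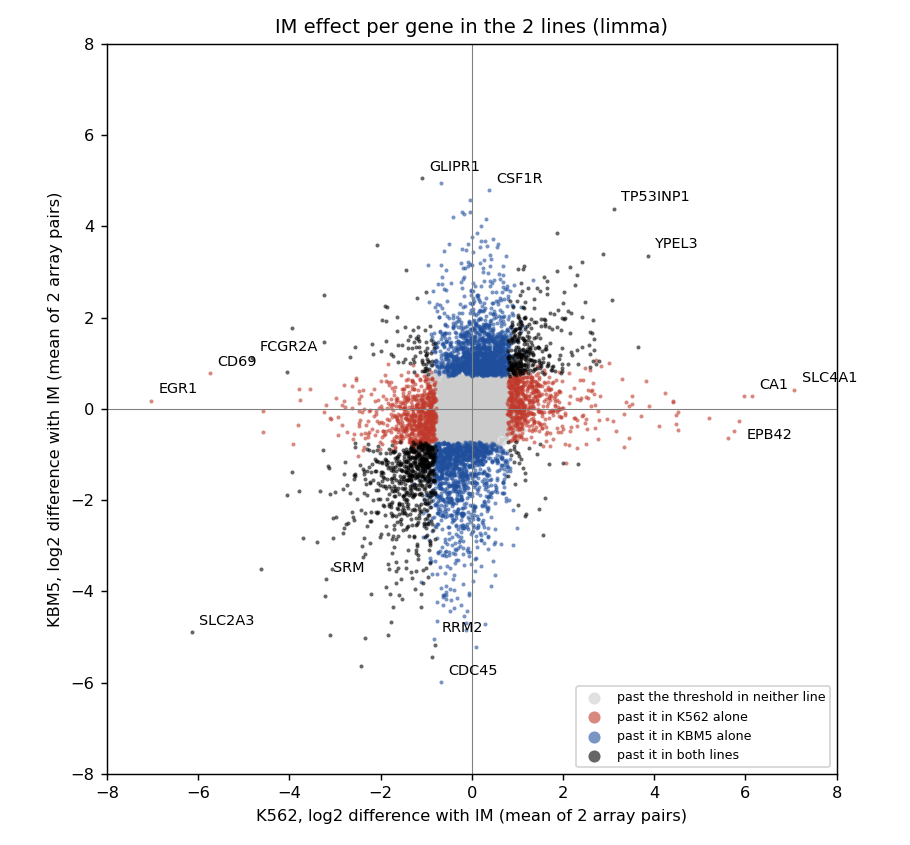
Effect of IM on each gene as the log2 difference in K562 (x axis) and KBM5 (y axis), each the mean of 2 array pairs. Of the 17687 genes, the 22 that are Y-linked, XIST or TSIX are not drawn. Colours show whether the gene was past the limma threshold in neither line (grey), K562 alone (red), KBM5 alone (blue) or both (black). SLC2A3 lies at -6.13 and -4.89, EGR1 at -7.02 in K562, SLC4A1 at 7.07 in K562 and CDC45 at -5.99 in KBM5. These positions are measured values, not bounds, and each of the 4 genes has arrays below background on 1 side of the differences named.

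OR21 was compared with its absence over the same 4 array pairs, to show what the demethylating agent did in both lines, and no gene passed the threshold. The genes named next were chosen for moving the same way in 4 of 4 pairs, so that agreement is no evidence of an effect. PPP1R27, a regulatory subunit gene of a phosphatase, was at least 4.69-fold and the histone gene H2BC14 at least 5.21-fold higher, both at background without OR21, as was LXN, a carboxypeptidase inhibitor. With OR21, PPP1R27 was above background on 3 of 4 arrays, H2BC14 on 3 and LXN on 1, in K562. TKTL1, a transketolase-like gene on many cancer-testis lists, had a log2 difference of 3.27 ± 0.79. The metal-binding metallothioneins MT2A and MT1B, paralogs whose probe sets may cross-hybridise, had 1.68 ± 0.28 and 1.42 ± 0.21, the T cell receptor transcript TARP 2.08 ± 0.29, MS4A3, a gene of granulocyte precursors, 1.62 ± 0.37, and the interleukin receptor IL23R 1.18 ± 0.23. TARP and MS4A3 were at background on all K562 arrays and IL23R on all KBM5 arrays, so for each of them 2 of the 4 pairs compare background with background. PNMA5, at background on both sides, had the smallest adjusted p, 0.707. On the lower side, the kinase gene AATK was at least 1.44-fold lower, at background with OR21, and SRR, a serine racemase at background on all KBM5 arrays, had -0.82 ± 0.21. MED12L, MACROH2A2, PWWP3B, LRRTM3, VN1R1, IQUB, PDE1C and HFM1 were at background on both sides.

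Limma called 0 genes with OR21 in both lines, with 622 at an unadjusted p under 0.05. In simulated data with the same design, 91.0% of 4-fold and 7.46% of 2-fold changes shared by both lines were recovered. Camera called 6 lists upward, namely G2/M (0.0101), erythroid (0.0081), granulocytic (0.0081), cancer-testis (0.0468), antigen presentation (0.0143) and lysosome genes (0.0351), and each had adjusted p = 0.84 with an estimated correlation. After quantile normalization the G2/M (0.0502) and lysosome (0.168) lists were not called. The G2/M direction reversed without the K562 control (adjusted p = 0.963) and without KBM5 IM (adjusted p = 0.26). Across genes, the OR21 pairs within a line had Pearson r = 0.189 in K562 and 0.268 in KBM5, and pairs of different lines r between 0.0527 and 0.103.

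In K562 alone, OR21 raised a small set of genes, of which 9 of 16 were at background without it, close to the 58.5% of all genes that were. H2BC14 went from an intensity of 18.9 to 20592 without IM and from 12.9 to 5283 with IM, at least 60.4-fold, though other histone genes may cross-hybridise with its probe set. TKTL1 rose by 5.28 ± 0.27 on the log2 scale, and GCNA, a germ cell nuclear protein gene, was at least 6.61-fold higher. The lipoxygenase gene ALOX12 was at least 2.68-fold higher, AKR1E2, an aldo-keto reductase gene, at least 2.18-fold, and LAPTM5, a lysosomal protein of blood cells, rose by 3.61 ± 0.30, with 1 of 2 arrays above background without OR21. Limma adjusted p of these 6 genes were between 1.58e-05 and 0.000658, with 2 of 2 pairs higher for each, as the naming rule requires. None of NAAA, PCCA, GPX8, PPM1H, SLC2A3 or SOSTDC1, the most steadily lower genes, passed, with adjusted p of 0.174 or more. NAAA, PCCA, GPX8 and PPM1H were at background on both sides, and SLC2A3 and SOSTDC1 had log2 differences of -1.23 and -1.45.

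Of 47 cancer-testis and germline genes 2 rose in K562 with OR21, TKTL1 and DPEP3 (at background on both sides), and 15 rose when adjusted over the list alone, while the germ cell gene DAZL was at background on both sides. Of the 47 genes, 28 were at background on all K562 arrays and 41 on all KBM5 arrays, which limits what these rises show. The list had a camera adjusted p of 1.05e-11, and adjusted p = 0.457 with an estimated correlation. AHSP, above background on 1 of 2 arrays of each side, rose by 2.08 ± 0.23 among 9 globin genes, and the blood group gene RHCE by 2.15 ± 0.28 among 23 erythroid genes, of which 7 rose over the list alone. The globin, heme and erythroid lists had camera adjusted p of 8.41e-05, 8.79e-06 and 1.05e-11 upward, and adjusted p = 0.692, 0.457 and 0.692 with an estimated correlation. Their medians in OR21 minus control were 1.65, 0.33 and 0.72 (percentile 100 of matched random lists for each), and in combination minus IM 0.23, 0.30 and 0.24 (percentiles 94.32, 99.79 and 99.11). JAK-STAT targets had a list median of -0.17 with no gene called in limma (camera adjusted p = 0.0442, and adjusted p = 0.693 with an estimated correlation), and the pairs differed, with -0.30 (percentile 0.11) in OR21 minus control and -0.05 (percentile 23.19) in combination minus IM. Of all genes, limma called 16 higher and 0 lower, with 863 at an unadjusted p under 0.05, and 47 genes rose and 4 fell at least 2-fold in both pairs. The 16 calls for the OR21 effect in K562 became 9 without the K562 control or OR21 array, 31 without any 1 KBM5 array, 4 among the brighter genes alone and 5 with 16 added to each value.

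In KBM5 alone, OR21 raised genes of granulocytes. MPO, the myeloperoxidase of neutrophil granules, went from an intensity of 65.8 to 11442 without IM and from 35.9 to 5282 with IM, at least 31.7-fold. PRG2, a major basic protein of eosinophil granules, was at least 16.7-fold higher, and CST7, a protease inhibitor of immune cells, rose by 4.80 ± 0.23 on the log2 scale. PPP1R27 was at least 28.2-fold higher, the potassium channel gene KCNH2 at least 8.46-fold, and the complement receptor C3AR1 at least 3.26-fold. Of 25 granulocytic and monocytic genes 5 rose, 11 when adjusted over the list alone, with the neutrophil protease CTSG at 2.40 ± 0.37 and MNDA at 2.12 ± 0.28, the latter above background on 1 of 2 arrays without OR21, and the granulocyte factor CEBPE, above background on 1 of the 4 KBM5 arrays, also called. The list had a camera adjusted p of 3.73e-07, and adjusted p = 0.651 with an estimated correlation. The stem cell factor GATA2 was at least 4.07-fold higher, the platelet adhesion gene THBS1 at least 1.41-fold, the kinase PIM2 at least 1.68-fold, and the lysosomal protease CTSD rose by 1.84 ± 0.24. On the other side, the chemokine receptor CCR2 fell by 2.60 ± 0.30, the nuclear protein gene AFF3 fell by 2.23 ± 0.32, and the monocyte factor IRF8 fell by 2.21 ± 0.35. The calcium-dependent kinase CAMK2D, above background on 1 of 2 arrays with OR21, fell by 1.97 ± 0.26 and TIFAB fell by 1.63 ± 0.25, while MANEAL was at background on both sides.

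Among other lists in KBM5 with OR21, G2/M genes had a list median of 0.43 with no single call in limma (camera adjusted p = 8.41e-06, and adjusted p = 0.78 with an estimated correlation). The 2 pairs differed, with a G2/M median of 0.03 in OR21 minus control, at percentile 52.92 of matched random lists, and of 0.87 in combination minus IM, at percentile 100. Lysosome genes had a median of 0.16, with 0.25 and 0.13 in the pairs, at percentiles 99.41 and 71.69 (camera adjusted p = 0.0202, 0.117 after quantile normalization, and adjusted p = 0.773 with an estimated correlation). Cholesterol genes had pair medians of -0.24 and -0.32, at percentiles 0.33 and 0 (camera adjusted p = 0.0729, 0.00574 after quantile normalization, and adjusted p = 0.773 with an estimated correlation), and antigen presentation genes 0.25 and 0.33, at percentiles 97.67 and 99.45 (camera adjusted p = 0.0563). Of the 47 cancer-testis genes none passed in limma in KBM5, where TKTL1 had 1.25 ± 0.27. Across all genes limma called 86 higher and 10 lower, and 139 genes rose and 27 fell at least 2-fold in both pairs. The 96 calls for the OR21 effect in KBM5 became 54 without any 1 K562 array, 157 without the KBM5 control or OR21 array, 62 among the brighter genes alone and 3 with 16 added to each value, where MPO, PRG2 and CST7 remained called. AFF3, IRF8, TIFAB and MANEAL lost their calls with at least 1 array left out.

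**Figure D3:**
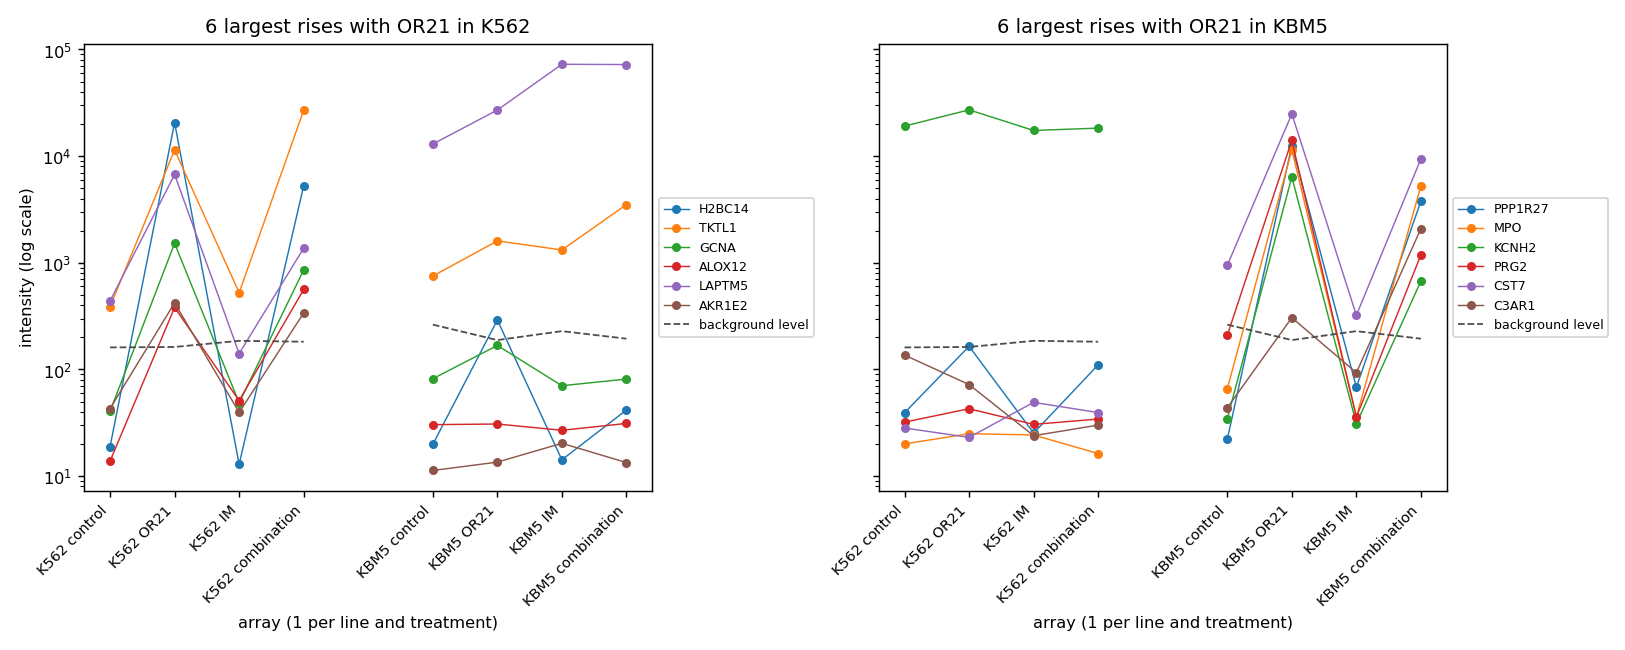
Intensity on a log axis of the 6 genes with the largest called rises with OR21 in K562 (left) and in KBM5 (right), on each of the 8 arrays, with the background level of each array as a dashed line. MPO lies at 65.8 and 35.9 on the KBM5 arrays without OR21 and at 11442 and 5282 on those with it.

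The effect of OR21 differed between the lines at 18 genes by the test of the difference (KBM5 minus K562, 8 positive and 10 negative). MPO, PRG2 and CST7, at background on all K562 arrays, had the larger rise in KBM5. TKTL1 (-4.03 ± 0.38), H2BC14, at background without OR21 in both lines, and GCNA, at background on all KBM5 arrays, had it in K562. Granulocytic genes differed upward (camera adjusted p = 1.69e-05) and cancer-testis genes, most of them at background, downward (7.92e-09), each with adjusted p = 0.441 with an estimated correlation. Only H2BC14, singled out after its values were seen, was called higher with OR21 in both lines, 1 gene where independence would give 0.0778. The 18 calls for the OR21 effect, KBM5 minus K562, became 6 without the K562 control or OR21 array, 12 without the K562 IM or combination array, 52 without the KBM5 control or OR21 array and 34 without the KBM5 IM or combination array.

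The combination was compared with the control over 1 array pair in each line, the sum of both drugs. YPEL3 rose by 4.41 ± 0.28 on the log2 scale, YPEL5 by 3.03 ± 0.33, CALCOCO1 by 3.23 ± 0.33, TMT1A by 2.94 ± 0.31 and PNRC1 by 2.86 ± 0.28. MAN2A2, a mannosidase of the Golgi, rose by 2.72 ± 0.30, the lysosomal ceramidase gene ASAH1 by 2.59 ± 0.24, the lipid transfer gene STARD10 by 2.38 ± 0.29, ICA1, a gene of secretory vesicles, by 2.14 ± 0.25, and DNAJC28 at least 1.44-fold. YPEL3, TMT1A, STARD10 and ICA1 were below background on the KBM5 control array and CALCOCO1 on the K562 control array, so 1 of the 2 pairs of each starts from background. DNAJC28 was at background on all KBM5 arrays. SLC2A3 was at least 62.1-fold lower, SLC2A14 fell by 4.70 ± 0.40, and LRP8 and ETV5 were at least 5.43-fold and 2.29-fold lower. POLR3G, a subunit of RNA polymerase III, fell by 3.16 ± 0.23, the arginine methyltransferase gene PRMT1 fell by 2.87 ± 0.34, and SLC7A1, a transporter of cationic amino acids, fell by 2.82 ± 0.33. LAPTM4B fell by 2.81 ± 0.34, the p53-induced nuclease gene AEN fell by 2.81 ± 0.31, and CHRNA5, a subunit of nicotinic receptors, was at least 1.81-fold lower. POLR3G, SLC7A1 and AEN were below background on the KBM5 combination array, so their falls are not exact.

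Within lists, 2 of 18 FOXO targets rose with the combination, 9 when adjusted over the list alone (camera adjusted p = 1.76e-10, and adjusted p = 0.0608 with an estimated correlation). MYC targets fell in 2 of 25, SRM and NOLC1, and in 18 over the list alone (camera adjusted p = 1.89e-18, and adjusted p = 0.0546 with an estimated correlation). Cholesterol genes fell in 15 of 20 over the list alone, though none passed over all genes in limma (camera adjusted p = 1.69e-11, and adjusted p = 0.346 with an estimated correlation). Lysosome genes rose in 8 of 27 over the list alone, where CTSD had 2.64 ± 0.54 (camera adjusted p = 5.05e-08, and adjusted p = 0.346 with an estimated correlation). Over all genes limma called 11 higher and 24 lower, with 2806 genes at an unadjusted p under 0.05. The 20 named genes had limma adjusted p between 0.0227 and 0.0491, with 2 of 2 pairs moving the same way, as the naming rule requires. Quantile normalization left 5 higher and 7 lower, or 41.7% higher in place of 31.4%. The 35 calls became 2 without the KBM5 combination array and 0 in limma without any other 1 array, where 1848 (without the KBM5 control) to 2740 genes had an unadjusted p under 0.05, and 0 with 16 added to each value.

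Against IM alone, which asks what OR21 added to IM, no gene passed in limma (605 at an unadjusted p under 0.05). LXN was at least 4.51-fold and PPP1R27 at least 3.15-fold higher, both at background with IM alone, as was the metallothionein MT1H. LXN was at background on all KBM5 arrays and PPP1R27 on the K562 combination array, so each bound rests on 1 line. The metallothionein MT1G had a log2 difference of 1.71 ± 0.29, and TARP 2.52 ± 0.41. On the lower side CCR2 had -2.10 ± 1.25 and POTEI -1.43 ± 0.28, NKD2 was at background with the combination, and HFM1 and MLH3 were at background on both sides. TARP and CCR2 were at background on all K562 arrays and POTEI on all KBM5 arrays. All 10 had an adjusted p of 1. Camera called G2/M genes (median 0.45, adjusted p = 0.00263, and adjusted p = 0.957 with an estimated correlation) and glycolysis genes (median 0.26, adjusted p = 0.0404, 0.0812 after quantile normalization, and adjusted p = 0.854 with an estimated correlation) upward. The G2/M call reversed its direction without KBM5 IM (adjusted p = 0.0168).

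Against OR21 alone, which asks what IM added to OR21, YPEL3 rose by 3.51 ± 0.28 on the log2 scale, TMT1A by 3.23 ± 0.31, YPEL5 by 2.88 ± 0.33, CALCOCO1 by 2.72 ± 0.33 and GTF2IRD2, from a family of near copies that may cross-hybridise, by 2.62 ± 0.27. SRM fell by 3.28 ± 0.31, SLC2A14 fell by 3.55 ± 0.40 and the nucleolar protein gene NOP16 fell by 3.02 ± 0.35, while LRP8 was at least 5.28-fold and ETV5 at least 2.14-fold lower, each of these 10 with limma adjusted p = 0.0444. MYC targets fell in 4 of 25 genes and in 19 over the list alone (camera adjusted p = 2.97e-21), a call that held with an estimated correlation (adjusted p = 0.0443). Among all genes limma called 9 higher and 30 lower, or 23.1% higher, against 7 and 9, or 43.8%, after quantile normalization. Without any 1 of the 8 arrays limma called 0, with 1319 (without KBM5 OR21) to 2479 genes at an unadjusted p under 0.05.

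The interaction, which asks whether the combination departed from the sum of both drugs on the log2 scale, had no gene past the threshold in limma, with 274 at an unadjusted p under 0.05. The survival gene BCL2 had 1.79 ± 0.52, HK2, a hexokinase, 1.75 ± 0.66, SLC7A5 1.70 ± 0.79, and the transcription factor EBF3 1.63 ± 0.41. The erythroid nuclear protein HEMGN had -1.82 ± 1.44, H2BC14 -1.87 ± 2.59 and the small heat shock protein CRYAB -1.73 ± 0.68. BCL2 and EBF3 were at background on all K562 arrays, HEMGN and CRYAB on all KBM5 arrays, LY6K on 7 of the 8 arrays, H2BC14 on 5, HK2 on 3, SLC7A5 on 1 (KBM5 IM), and the growth factor gene EREG and COL9A1 on all 8. All 10 had an adjusted p of 1. Camera called amino acid stress and glycolysis genes upward (adjusted p = 0.00368 for each), with adjusted p = 0.693 and 0.947 with an estimated correlation. Of their members DDIT4, above background on all 8 arrays, had 1.57 ± 0.68. Each value of the interaction rests on all 8 arrays with 1 array per group, and its median SE over genes was 0.423, against 0.211 for the effect of IM.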

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

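Of the tests below, those on the excess of falls with IM and on the other line's RNA in the KBM5 arrays with OR21 were chosen only after the result was seen. No group held enough arrays for a search for outlying samples.

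The effect of IM differed between the lines by the test of the difference at 1796 genes, and that of OR21 at 18. With IM, 108 genes were called in opposite directions in the lines with the difference called too. By list, the difference with IM was called at 25 G1/S, 21 G2/M, 14 heme, 14 erythroid, 12 JAK-STAT, 11 histone, 10 granulocytic, 10 cholesterol, 9 ERK and 9 amino acid stress genes. It was also called at 8 interferon-stimulated, 7 lysosome, 6 globin, 5 cancer-testis, 5 DNA methylation and 5 NF-kB genes. The difference was positive at 7 of the ERK genes, of which 6 were at background on all KBM5 arrays. The log2 difference (KBM5 minus K562) with IM was 7.205 for EGR1, 6.52 for CD69, 6.155 for GLIPR1, 5.929 for FCGR2A, 5.744 for PRKCB and 5.716 for LCP2. At the other end it was -6.649 for SLC4A1, -6.253 for CYP3A5, -6.22 for TUBB1, -6.119 for EPB42, -5.855 for CA1 and -5.68 for ALAS2. With OR21 it was 7.452 for MPO, 5.695 for KCNH2, 5.379 for PPP1R27, 5.274 for PRG2, 5.102 for CST7 and 3.942 for C3AR1, and -6.669 for H2BC14, -4.064 for GCNA, -4.027 for TKTL1, -4.007 for ALOX12, -3.365 for AKR1E2 and -3.239 for AQP1. These sizes are not exact, since all of these genes but FCGR2A and TKTL1 were below background on some arrays, EGR1 and CD69 for instance on all KBM5 arrays and on both K562 arrays with IM. KCNH2, PPP1R27, C3AR1, GCNA, ALOX12, AKR1E2 and AQP1 lost this call with at least 1 array left out. Among the 3739 transcript clusters with no name here, which the comparisons did not use, 51 were called higher and 88 lower with IM in both lines, and 1 was called higher with OR21 in KBM5.

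The 8 arrays can be split into 4 and 4 in 35 ways, of which 34 could be fitted beside a term for the line. The split by IM called 2342 genes in this simpler model, the highest other split called 0, and 1 of the 34 gave as many as the real one, itself. Only 18 of the splits have 2 arrays of each line on each side, as the real one has. Of these 18, 1 gave as many, again the real one, and 18 are too few for a share under 5%. Each other split also leaves the effect of IM in the residual, which by itself favours a count of 0. Chance is therefore not excluded for the IM calls by this test. The split by OR21 called 0 in limma, where the model with all treatments had 622 genes at an unadjusted p under 0.05, and all 34 splits gave as many, which a real count of 0 fixes in advance, so this says nothing about chance for OR21. The highest other split, with 2342, is the split by IM, a structure of the samples.

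S-phase genes fell with IM in KBM5. If scaling of the arrays were the cause, matched random lists would fall as far, but the G1/S median lay at percentile 0 of 10000 such lists in both KBM5 pairs. If the KBM5 arrays with IM held K562 RNA, 127 genes much brighter in K562 would move towards the K562 level, but their median position between KBM5 (0) and K562 (1) was 0.0258 on the IM array and 0.00271 on the combination array. K562 RNA would not lower S-phase genes in any case, so this test adds no support. The G1/S median of KBM5 minus K562 was 0.00 in the control arrays and -3.03 with IM. A stronger arrest of the cycle in KBM5 than in K562 may be a biological explanation, which remains a hypothesis since it rests on 1 array per group. DNA content of cells counted in repeated cultures of both lines with IM would test it.

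More genes fell than rose with IM in both lines, 862 against 487. After quantile normalization 48.66% of calls were higher, in place of 36.1%. That step gives all arrays the same distribution and would remove a true excess of falls as well, so this does not tell the authors' normalization from a true excess. The median log2 difference over all genes was 0.06. The median gene was below background on every array, so this value cannot show whether expressed genes carried an offset. The positive control probe sets had lower median log2 intensities with IM. In K562 these were 12.308 (IM) and 12.324 (combination) against 12.728 (control) and 12.765 (OR21). In KBM5 they were 12.082 and 12.264 against 12.546 and 12.572. Both explanations stay open.

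Granulocytic genes rose with OR21 in KBM5. If the KBM5 control array were aberrant, the rise would be missing in combination minus IM, which does not use it, but the list's median lay at percentile 99.98 there. If K562 RNA were the source, most of the genes called higher would be as bright on some K562 array, but 29.1% (25 of 86) were. For the granulocytic and monocytic list this test adds little, since 21 of its 25 genes were at background on all K562 arrays. An effect of OR21 on granulocytic differentiation of KBM5 may be an explanation and remains a hypothesis. Granulocytic surface markers and cell morphology in repeated cultures with and without OR21 would test it.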

How the results depend on the processing

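No alternative here was chosen only after the result was seen. The calls for the IM effect in KBM5 (3780) stayed within 1.5 times under all alternatives (2722 to 3245 with 1 array left out). In limma, OR21 in both lines, the combination against IM and the interaction gave 0 calls under all 14 alternatives, with 185 to 1002, 168 to 1066 and 50 to 540 genes at an unadjusted p under 0.05. Causes below were not tested unless stated. Without the line in the model, the IM effect, both lines (1349), the combination against control, both lines (35) and the combination against OR21 alone, both lines (39) had 0 calls in limma, with 1603, 905 and 806 genes at an unadjusted p under 0.05, since the line difference then enters the residual by construction. Quantile normalization left 12 for the combination against control and 16 against OR21. With log2(value + 16) the combination against control had 0 (2828 at an unadjusted p under 0.05), the OR21 effect in K562 (16) had 5, the OR21 effect in KBM5 (96) had 3, and the OR21 effect, KBM5 minus K562 (18) had 2. The brighter genes alone gave 22 for the combination against control, 4, 62 and 6 for those OR21 contrasts. Trend and robust moderation gave 27, 243 and 43 for them, and a common OR21 by IM term 32 in K562 and 149 in KBM5. With 1 array left out, a line's effect rests on fewer arrays by construction. The range was 115 (without KBM5 OR21) to 557 (without the K562 control) for IM in both lines, 0 (without each of the other 7 arrays) to 2 (without the KBM5 combination) for the combination against control, and 0 to 0 against OR21, where 1319 to 2479 genes had an unadjusted p under 0.05. It was 454 (without the K562 control or IM) to 3201 (without any KBM5 array) for the IM effect in K562 (2368), and 611 (without the K562 control or IM) to 1804 (without KBM5 OR21 or combination) for the IM effect, KBM5 minus K562 (1796). For OR21 it was 9 (without the K562 control or OR21) to 31 (without any KBM5 array) in K562, 54 (without any K562 array) to 157 (without the KBM5 control or OR21) in KBM5, and 6 (without the K562 control or OR21) to 52 (without the KBM5 control or OR21) for the difference. For genes changed 2-fold, IM, K562, no test (1222), 1.5-fold and 3-fold gave 3005 and 403, and for IM in KBM5 (genes changed 2-fold, IM, KBM5, no test, 1979) 3770 and 820, by construction. For genes changed 2-fold, OR21, K562, no test (51), they gave 308 and 14, the brighter genes 32 and log2(value + 16) 31, and for genes changed 2-fold, OR21, KBM5, no test (166) 804 and 34. Of 118 list calls, 2 held with an estimated correlation and 116 did not, and 104 held after quantile normalization and 14 did not. With each array left out in turn, 838 list results were kept, 100 lost and 6 reversed. The shift of G2/M genes with OR21 in both lines had an adjusted p between 2.91e-12 (without K562 IM) and 0.963 (without the K562 control, reversed), and 0.26 without KBM5 IM, reversed too. Globins with the combination against control reversed without the K562 control (adjusted p = 0.61, range 7.29e-07 without the KBM5 control to 0.954 without the K562 combination). G2/M with the combination against IM reversed without KBM5 IM (adjusted p = 0.0168, range 2.36e-15 without K562 IM to 0.498 without the K562 combination), and G2/M in the line difference with OR21 reversed without KBM5 IM or KBM5 combination (adjusted p = 0.605, range from 9.48e-08 without the KBM5 control or OR21). Of the named genes with a call, 101 kept it after quantile normalization and 15 lost it, 68 and 48 with log2(value + 16), and 113 and 3 with trend and robust moderation. Among the brighter genes 94 kept it and 11 lost it, all 116 kept it with the mean of a gene's probe sets, and 50 of 50 lost it without the line. The mean of probe sets alters only the 20 genes with more than 1 probe set, so that agreement was largely fixed in advance. Background limits the folds of genes at or below it on one side, for which a bound is given.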

Other observations

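Of the tests below, the 2 on genes silent before OR21 were chosen only after the result was seen, and the one on X-linked genes before.

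The lines differed without drug as well, given as values with no test. In the control arrays the list median of KBM5 minus K562 was -5.67 on the log2 scale for globins, -3.43 for erythroid genes, 1.69 for granulocytic and monocytic genes and 0.00 for G1/S genes, and with the combination it was -10.5, -6.31, 4.75 and -2.98. These sizes are not exact for the lineage lists, since 9 of 9 globin and 17 of 23 erythroid genes were at background on all KBM5 arrays and 21 of 25 granulocytic and monocytic genes on all K562 arrays.

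OR21 raised genes that were below background, and 3 hypotheses about them were tested with Fisher's exact test, two-sided, over genes, which are not independent replicates, in a family of 8 tests. The first was that OR21 acts mostly on genes silent in the line, with IM as the comparison. Of the genes called higher with OR21 in K562, 56.2% (9 of 16) were not above background on both arrays without OR21, against 38.3% (359 of 938) of those called higher with IM but not with OR21 on both arrays without IM (exact p = 0.194, adjusted p = 0.222), and in KBM5 58.1% (50 of 86) against 38.9% (732 of 1882, exact p = 0.000447, adjusted p = 0.00179). An earlier definition, replaced after its result was seen, used the arrays without OR21 for both drugs and gave 27.3% (256 of 938, exact p = 0.0199, adjusted p = 0.0318) in K562 and 26.4% (496 of 1882, exact p = 1.64e-09, adjusted p = 1.31e-08) in KBM5. It was replaced because those arrays include one with IM, on which genes raised by IM are above background by construction. Over all 17687 genes the share not above background on both arrays without OR21 was 58.5% in K562 and 62.5% in KBM5, so the genes raised by OR21 were silent no more often than genes at large. The comparison with IM passed in KBM5 alone, where genes raised by IM were silent less often than genes at large (38.9% against 62% on the arrays without IM). A preference of OR21 for silent genes is therefore not shown in either line, and K562 has only 16 genes raised by OR21.

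The second was that silent genes raised by OR21 are those the other line expresses. In KBM5 22% of them (11 of 50) were above background on both K562 arrays without OR21, against 7.67% (844 of 10998) of other silent genes (exact p = 0.00127, adjusted p = 0.00339). In K562 it was 0 of 9 against 3.51% (363 of 10333, exact p = 1, adjusted p = 1). The difference in KBM5 may be partly built in. The other silent genes include genes at background on all 8 arrays, which cannot count as expressed in K562, and silent genes raised by IM were not compared. The third was that X-linked genes are over-represented among genes at least 2-fold higher with OR21 in both pairs. In K562 14.9% (7 of 47) were X-linked against 3.98% of other genes (exact p = 0.00253, adjusted p = 0.00506), and in KBM5 6.47% (9 of 139) against 3.99% (exact p = 0.13, adjusted p = 0.173), so it stays open.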
